A study of Mus musculus with 2 samples.

How the data were processed

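RNA was extracted with Trizol from sorted CCR2+ and CCR2− splenic macrophages of C57BL6 mice on day 3 of infection with Listeria monocytogenes, per the labels. The extraction protocol in the labels names the cells by another abbreviation, PM, than the other labels, which name splenic macrophages (SM). The cells are taken to be splenic macrophages here, and this conflict was not resolved. Biotin-labelled cRNA was prepared from total RNA and hybridised to Affymetrix mouse arrays, 1 array per group. The number of mice behind each sample, the sorting gates apart from CCR2, the purity of the sorted cells and the array batch are not given in the sources used here. The deposited values are intensity signals on a linear scale, 1 per probe set, made with MAS5, per the submitters' processing notes. MAS5 is Affymetrix's algorithm that combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array by a constant. Its version, scaling target and detection calls are not given in the sources used here. The means after trimming 2% at each end were 102.2 on the CCR2+ array and 100.9 on the CCR2− array. Because the arrays are scaled to a common level, a very abundant group of transcripts in 1 sample lowers the values of the others there, and low signals after mismatch correction are noisy. This is why a background floor was used.

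The table holds 45101 probe sets, of which 64 are controls. By the platform annotation, 34958 probe sets have 1 gene symbol, 932 have several and 9211 have none. Genes were named from probe sets with 1 symbol alone. Of these probe sets, 34754 had an Entrez identifier in the RefSeq gene table (assembly GRCm38.p6, used for names and for genomic spans), and 0 symbols needed updating. This gave 18193 genes. Among the 9160 probe sets that are neither controls nor named here, 1567 were measured, with 43 at least 2-fold higher in CCR2+ cells and 72 at least 2-fold higher in CCR2− cells.

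The floor was the 95th percentile of the signals, on both arrays, of 129 probe sets for 115 genes of olfactory, vomeronasal and taste receptors and keratin-associated proteins, which spleen cells should lack. It came to 85.4. Values under it were raised to it before log2 was taken, and a ratio with 1 such value is a bound, written as at least N-fold. A gene was measured if at least 1 array reached the floor, and a gene with several probe sets was represented by the one with the highest mean signal. This selected 8081 genes, 44.4% of all. Their signals correlated at a Pearson r of 0.87 across genes, which are not replicates. The signals were used as deposited. The median log2 ratio of measured genes was 0.06, so values are not centred at 0.

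With 1 array per group no test is possible, so no p-values are given, and genes are described by a fixed rule of size, an absolute log2 ratio of at least 1. For gene lists, the median log2 ratio of the measured members was ranked among 10000 random lists of the same size, drawn from the measured genes in 20 bins of mean log2 signal. A list needed 3 measured members and was placed apart from random lists when it lay in the outer 2.5% on either side. Such a rank describes these arrays and says nothing about other animals. The design, the rules, 38 gene lists and the alternatives were fixed before the data were examined. The lists were classical and non-classical monocyte, red pulp and marginal zone macrophage, conventional and plasmacytoid dendritic cell, neutrophil, B cell, plasma cell, T cell, NK cell, basophil with mast cell and eosinophil, erythroid, platelet, and endothelial and stromal markers. Further lists held inflammatory cytokines, chemokines, chemokine receptors, antimicrobial effectors, type I interferon-stimulated genes, interferon-gamma response, MHC class II and costimulation, alternative activation, pattern recognition and inflammasome, complement and Fc receptors, iron and haem, lipid and cholesterol, lysosome and cathepsins, cell cycle, glycolysis, oxidative phosphorylation, myeloid transcription factors, adhesion and migration, immediate early and stress response, and cell death and survival. Ribosomal protein, housekeeping and sex-linked genes served as controls. Of 656 list entries, 67 matched no gene with a probe set of its own. Some genes stand in several lists.

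The named genes were the 12 with the highest and the 12 with the lowest ratio among genes at or above the floor on both arrays, the 6 with the largest bound in each direction, Ccr2, and in each list the 2 to 4 measured members with the largest absolute log2 ratio. Symbols of clones and gene models were counted and not named, and 21 of the genes at least 2-fold apart were of this kind. Probe set agreement was taken as the share of genes at least 2-fold apart whose second measured probe set lay on the same side, with exact Clopper-Pearson 95% intervals. RNA quality was read from the 3′ and 5′ control probe sets of Gapdh and Actb, and hybridisation from the spiked controls. Alternatives covered the scaling of the arrays (centring on the median, quantile normalisation, and a loess curve on mean signal with a span of 0.3), the floor, the probe set rule, the fold threshold, the filter, unmatched random lists and lists without shared genes. No genome build is named for the probe sets, so no positions are given.

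The scripts were tested on simulated data for the comparison of CCR2+ with CCR2−. Among 7954 simulated measured genes with a noise SD of 0.4 on the log2 scale, all 200 genes changed 4-fold were recovered (100%). Of 7754 unchanged genes, 1.07% passed 2-fold. The changed genes were drawn only from those with real signals above 400 on both arrays, so weaker genes and bounds were not covered. The log2 ratios of the real measured genes had an SD of 0.60, so these shares need not hold for them. The simulated lists held 15 genes drawn at random, with noise that was independent between genes. Of 400 unchanged lists, 4.25% were placed apart from random lists, and of lists shifted by 0.5, 98.5% were. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.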

Results

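Gene expression was measured in splenic macrophages sorted from C57BL6 mice on day 3 of an in vivo infection with Listeria monocytogenes, a bacterium that multiplies inside phagocytes. The cells were split by CCR2, the receptor for the chemokine CCL2 that guides monocytes out of the bone marrow. One sorted sample was CCR2+ and the other CCR2−, and each was hybridised to 1 Affymetrix array. There were no replicates, so the differences have no replicate check, and the values below describe these 2 arrays. Signals ranged from 1 to 9221 on the CCR2+ array and from 1 to 25995 on the CCR2− array, with medians of 39.9 and 40.4. Of 18193 genes with a probe set of their own, 8081 reached the background floor of 85.4 on at least 1 array, with 6676 on both, 828 on the CCR2+ array alone and 577 on the CCR2− array alone.

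The comparison asks how the CCR2+ and CCR2− populations of the infected spleen differ in their transcripts. Ccr2 itself, the sort marker and therefore a check of the labels and no finding, had a signal of 542 in the CCR2+ sample and 71.0 in the CCR2− sample. The second value lies under the floor, so Ccr2 was at least 6.34-fold higher in the CCR2+ sample. A second Ccr2 probe set read 179 against 96.5, a smaller gap in the same direction, and the median of both gave a log2 ratio of 1.78 in place of 2.66. Across the measured genes, 371 were at least 2-fold higher in the CCR2+ sample and 368 at least 2-fold higher in the CCR2− sample, of which 64 and 59 rest on a bound because 1 array was under the floor. Differences of at least 4-fold were seen for 21 and 29 genes. The remaining 7342 genes lay under 2-fold, and the SD of the log2 ratio over all measured genes was 0.60.

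Among genes measured on both arrays, the largest ratio in favour of the CCR2+ sample belonged to Lpl, the lipoprotein lipase that releases fatty acids from circulating triglycerides. Its signal was 1003 in CCR2+ cells and 99.9 in CCR2− cells, a log2 ratio of 3.33. S100a4, a calcium-binding protein of migrating cells, read 1408 against 155 (9.10-fold), and F13a1, the coagulation factor XIII A chain made by monocytes and macrophages, read 1452 against 195 (7.45-fold). Htra2, a mitochondrial serine protease, was 8.19-fold higher, with a smaller gap of 335 against 131 on its other probe set. Tmem51 followed at 6.42-fold, and the cell surface receptor Slamf8 at 4.45-fold. The LIM-domain protein gene Crip1 read 2197 against 502, and the transcription factor Maf 464 against 107. Stx3, a membrane fusion protein, and Rassf4 were each 4.19-fold higher, Aif1, which encodes the macrophage protein IBA1, 4.10-fold, and the mitochondrial ribosomal protein gene Mrpl52 4.07-fold. For Mrpl52, 1 of its 4 probe sets read slightly lower in CCR2+ cells, at 164 against 174. Genes under the floor in CCR2− cells included the scavenger receptor Msr1 and the matrix proteoglycan Vcan, each at least 4.89-fold higher in the CCR2+ sample. The cytokine receptor chain Il6st was at least 4.50-fold and the VEGF receptor Flt1 at least 4.39-fold higher, though a second Flt1 probe set read 90.8 against 54.7. Hivep3 was at least 5.11-fold higher by its strongest probe set alone, while the next one read 248 against 223 and the third 87.3 against 113.

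In the CCR2− sample the largest difference among genes measured on both arrays belonged to Niban1, a stress-response gene, with a signal of 1298 against 112 (11.6-fold), and 452 against 151 on its other probe set. Hdc, the histidine decarboxylase that makes histamine, read 6384 against 822 (7.76-fold), and 3886 against 1699 on its other probe set. Several of the next genes are known from neutrophils. Cd177, a neutrophil surface glycoprotein, was 6.50-fold higher in CCR2− cells, Ceacam10 5.83-fold, Itgb2l 5.26-fold, and Olfm4, a protein of neutrophil granules, 5.17-fold. Prok2, a chemokine-like peptide made by neutrophils, was 4.89-fold higher, and Padi4, the enzyme that citrullinates histones in neutrophils, 4.71-fold. The adhesion molecule gene Selp was 4.74-fold, Rflnb 5.49-fold and Dmxl2 4.43-fold higher in the CCR2− sample. Arap3 was 4.66-fold higher by its strongest probe set, which can take RNA of other genes, and its other probe sets read 186 against 116 and 184 against 32.9. Among genes under the floor in CCR2+ cells, Nlrp12, a regulator of inflammation in myeloid cells, was at least 4.50-fold higher in CCR2− cells, Mgam at least 4.59-fold, Scrg1 at least 4.99-fold and Rnf25 at least 5.17-fold. Suds3 was at least 7.17-fold higher by 1 probe set and read 141 against 114 on the other. Dnajc28 had a signal of 24553 in CCR2− cells and 4.86 in CCR2+ cells by 1 probe set, while its other probe set lay under the floor on both arrays, at 41.4 and 30.2. An array artefact at the first probe set was not excluded.

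**Figure D1:**
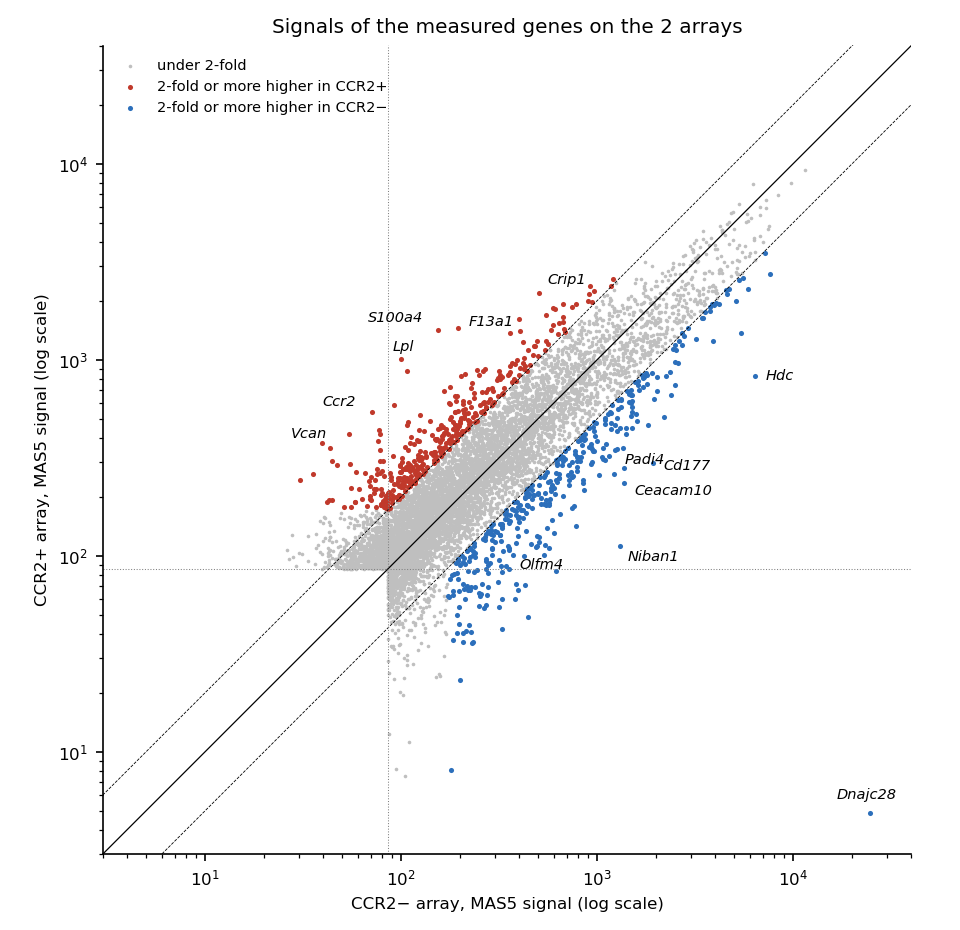
Signals of the 8081 measured genes on the CCR2− array (x axis, MAS5 signal, log scale) and the CCR2+ array (y axis, MAS5 signal, log scale), 1 point per gene. Red points are the 371 genes at least 2-fold higher in CCR2+ cells and blue points the 368 genes at least 2-fold higher in CCR2− cells, after values under the floor of 85.4 (dotted lines) were raised to it. The solid line marks equal signals and the dashed lines 2-fold differences. Lpl, S100a4 and F13a1 stand far above the solid line, and Niban1, Hdc and Cd177 far below it.

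Gene lists fixed before the data were examined were then compared through the median log2 ratio of their measured members, CCR2+ over CCR2−, which was ranked among 10000 random lists of the same size and matched signal. Of 34 lists with at least 3 measured members, 6 lay in the highest 2.5% of random lists and 9 in the lowest. If genes varied independently, 1.7 lists in all would be placed so by chance. Genes of a list can vary together and some lists share genes, so a common difference can place several lists at once. These counts are therefore no test. Csf1r and the genes named beside the 4 largest ratios of a list were chosen after their values were seen. Pairs of signals are given as CCR2+ against CCR2− unless named.

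Both sorted samples held transcripts of several cell types. The neutrophil granule gene Ngp read 2724 in CCR2+ and 7608 in CCR2− cells, the B cell gene Ms4a1 2100.2 and 1484, and the cytotoxic lymphocyte gene Gzma 1561 and 2852. Of the macrophage genes, Csf1r, the receptor for the macrophage growth factor CSF1, read 2590.0 and 1674. Adgre1, which encodes F4/80, read 153 and 107, Mertk 122 and 50.2 and Vcam1 93.8 and 81.2, against a floor of 85.4. Of 19 genes of the red pulp macrophage list on the array, 14 were measured, with median signals of 139 and 107. Spic, Cd163, Hpgd, Fcna and Pparg were under the floor on both arrays by their strongest probe set. The strongest genes of the list were Slc11a1 (1012 and 1072) and Slc40a1 (528 and 1575).

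Neutrophil markers were the list furthest toward the CCR2− sample. Of 16 measured members, 10 were at least 2-fold higher in CCR2− cells and 0 in CCR2+ cells, and the median log2 ratio was −1.07, lower than all 10000 random lists. The chemokine receptor Cxcr2 read 2186 in CCR2− cells against 510.3 in CCR2+ cells, the granule protein lactoferrin (Ltf) 5389 against 1367, the gelatinase Mmp9 2496 against 746 and the granule protein Ngp 7608 against 2724. The calprotectin subunit genes S100a8 and S100a9 had signals of 7980 and 9221 in CCR2+ cells and 9767 and 11426 in CCR2− cells. The signal of S100a9 was the highest on the CCR2+ array, and saturation was not excluded there. The primary granule genes Mpo, Prtn3 and Elane, which are transcribed in early precursors, did not share the direction of the list, with log2 ratios of 0.11, 0.22 and 0.49. The list of basophil, mast cell and eosinophil markers had 4 measured members and a median of −0.43, inside the random range, with Hdc and Siglecf (log2 ratio at most −0.98) at its lower end. Its direction turned with the floor at the median of all signals (0.19), with the floor at the 75th percentile (0.29) and without probe sets that can take several genes (0.13), while after quantile normalisation it lay in the lowest 2.5% of random lists (−0.49).

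Monocyte genes went both ways. In the classical monocyte list, S100a4, F13a1, Vcan and the fibronectin gene Fn1 were at least 2-fold higher in CCR2+ cells, whereas Cd177, Thbs1, Gsr, Ifitm6 and Hp were at least 2-fold higher in CCR2− cells, and Cd177 and Hp are also transcribed in neutrophils. The list median was −0.59 over 17 genes, in the lowest 2.5% of random lists, a placement that held under 7 of 10 alternative settings. The non-classical monocyte list lay at −0.36 over 8 genes, inside the random range, with Pglyrp1 at 1273 against 3188, Pou2f2 at a log2 ratio of at least 0.80 and Cebpb at −0.61. Red pulp macrophage genes had a median of 0.21 over 14 genes, also inside that range. Within it, Maf, the complement component C1qb (435 against 123) and the secreted scavenger protein Cd5l (263 against 77.6, under the floor) were higher in CCR2+ cells, and the iron exporter Slc40a1 was higher in CCR2− cells (528 against 1575). With other floors this list lay in the highest 2.5% of random lists, with a median of 0.59 at the 99th percentile, 0.47 at the median of all signals and 0.43 at the 75th percentile. Alternative activation genes gave 0.17 over 8 genes, led by F13a1, Tgfb1 at a log2 ratio of at least 1.09 and Klf4 at 1.01. Myeloid transcription factor genes gave 0.21 over 18 genes, with Maf, Klf4, Irf4 (log2 ratio at least 0.98) and Irf8 (0.96) toward CCR2+ and Cebpd (−1.54) toward CCR2−. Conventional dendritic cell genes had a median of 0.09 over 8 genes, with Dpp4 at 1.19, Ccr7 at 1.16 and Cd24a at −0.89. Plasmacytoid dendritic cell genes had a median of 0.02 over 6 genes, with Tcf4 at 0.99 and Ly6d at 0.91. The marginal zone macrophage list had 6 genes on the array, of which 2 were measured, and was not ranked. The measured members were Tgm2 (1637 in CCR2+ cells, 1908 in CCR2− cells) and Nr1h3 (92.7 and 88.4). Marco, Siglec1, Cd209b and Cd209d were under the floor on both arrays by their strongest probe set.

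Genes of MHC class II antigen presentation were higher in the CCR2+ sample. The MHC class II and costimulation list had a median log2 ratio of 0.67 over 13 genes, higher than all 10000 random lists, with 12 members above 0 and 4 at least 2-fold higher. These were the costimulatory receptor Cd40 (451 against 162), the costimulatory ligand Cd86 (284 against 105), the peptide-loading chaperone gene H2-DMa (1175 against 478) and Ciita, the master regulator of MHC class II transcription (324 against 134). The class II chain genes H2-Aa and H2-Ab1 and the invariant chain gene Cd74 had log2 ratios of 0.16, 0.36 and 0.35. The protease gene Ctss was the 1 member below 0, at −0.33. B cell markers, which share much of this program, moved in the same direction. All 15 measured B cell genes were above 0 and under 2-fold, with a median of 0.64, and 4 of 10000 random lists were as high. Blk, Vpreb3 (a bound), Cd22 and Pou2af1 led with log2 ratios of 0.80, 0.78, 0.77 and 0.74, and Ms4a1, which encodes CD20, stood at 0.50. Plasma cell genes had a median of 0.66 over 4 genes, led by Mzb1 (876 against 450.1) and Jchain (1394 against 826), a placement that held under 7 of 10 alternatives.

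NK cell genes were higher in the CCR2− sample. They had a median of −0.78 over 12 genes, lower than all 10000 random lists, with 4 members at least 2-fold higher in CCR2− cells. Perforin (Prf1, 68.8 against 237) and the activating receptor gene Ncr1 (55.0 against 197) were bounds, being under the floor in CCR2+ cells, granzyme B (Gzmb) read 815 against 1721, and Nkg7 354 against 711. T cell genes had a median of 0.23 over 9 genes, inside the random range at percentile 97.4, with 8 members above 0 and the CD3 chain genes Cd3g (243 against 103) and Cd3d (337 against 148) at least 2-fold higher in CCR2+ cells. Under 4 of 10 alternatives this list lay in the highest 2.5% of random lists, with a median of 0.87 with the floor at the 99th percentile and 0.37 after loess.

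Inflammatory cytokine genes were lower in the CCR2+ sample, with a median of −0.52 over 12 genes and 56 of 10000 random lists as low. Oncostatin M (Osm) read 257 in CCR2+ and 1015 in CCR2− cells, Il15 170.3 and 409, Il1b 2763 and 5466, and Csf1 358 and 709, while Il18 had a log2 ratio of 0.70 in the other direction. Pattern recognition and inflammasome genes had a median of −0.61 over 18 genes. Tlr4, Tlr13 and the LPS co-receptor gene Cd14 (1754 against 3544) were at least 2-fold higher in CCR2− cells, and Msr1 and the DNA-sensing adaptor gene Sting1 (649 against 193) at least 2-fold higher in CCR2+ cells. This list kept its place under 9 of 10 alternatives. Complement and Fc receptor genes also lay low, at −0.63 over 14 genes, with members on both sides of 0. The properdin gene Cfp, the C5a receptor gene C5ar1 and the integrin gene Itgam had log2 ratios of −1.22, −1.21 and −1.12, whereas C1qb, C1qc and the high-affinity IgG receptor gene Fcgr1 stood at 1.82, at least 1.41 and 1.36. The other IgG receptor genes Fcgr3, Fcgr4 and Fcgr2b had log2 ratios of −0.90, −0.83 and 0.28. Immediate early and stress response genes gave −0.68 over 17 genes, 11 of them below 0, with Ier2 at −1.17, Fos at −0.93, Btg2 at −0.87 and Dusp1 at −0.87. The heat shock genes Hspa1a, Hspa1b, Dnajb1 and Hspa8 went the other way, at 0.80, 0.49, 0.48 and 0.32. The list kept its place under 9 of 10 alternatives. In all 4 of these lists the direction was the same as that of the neutrophil markers, at −1.07.

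Type I interferon-stimulated genes were lower in CCR2+ cells, with 18 of 20 below 0, a median of −0.59 and 63 of 10000 random lists as low. The neutrophil markers, at −1.07, had the same direction. Cmpk2 read 539 against 1164 and Ifit3 1621 against 3423. The antiviral GTPase gene Mx1 was an exception, at 590.4 in CCR2+ and 206 in CCR2− cells. Interferon-gamma response genes had a median of −0.31 over 17 genes, inside the random range. Cxcl9, a chemokine that draws activated T cells, read 1861 against 747, Ciita had a log2 ratio of 1.27, and the feedback inhibitor Socs1 read 229 against 465. Antimicrobial effector genes, with a median of −0.48 over 16 genes, were also inside it, with the siderophore-binding Lcn2 at −1.03, Gbp2 at −0.82, Irgm2 at −0.81 and Igtp at −0.77. Chemokine genes had a median of −0.22 over 14 genes, with Ccl9 (log2 ratio 1.40) and Cxcl9 at least 2-fold higher in CCR2+ cells and Ccl6 at −0.86. Chemokine receptor genes had a median of −0.31 over 9 genes, with Cxcr2 and Ccr1 (−0.96) toward CCR2− and Ccr7 toward CCR2+. Adhesion and migration genes gave −0.21 over 13 genes, led by Itgam, the selectin ligand gene Selplg (−1.08) and Alcam (−0.94). Cell death and survival genes gave −0.13 over 14 genes, with the necroptosis effector Mlkl at 0.97 and the survival factor Mcl1 at −0.81. None of these 4 lists left the random range.

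Respiratory chain genes were higher in the CCR2+ sample. The oxidative phosphorylation list had a median log2 ratio of 0.60, higher than all 10000 random lists, with 20 of 21 genes above 0 and 4 at least 2-fold higher. These were the complex I subunit genes Ndufb5 (838 against 350) and Ndufv1 (408 against 181), Ndufa4 (1564 against 666) and the cytochrome c gene Cycs (1958 against 935). The 3′ to 5′ signal ratio, a sign of RNA integrity or of incomplete labelling, was also higher in the CCR2+ sample, at 1.26 against 0.99 for Gapdh and 2.14 against 1.32 for Actb. Cell type markers differed as well, with list medians of 0.64 for B cells, 0.66 for plasma cells, −1.07 for neutrophils and −0.78 for NK cells. Glycolysis genes lay at −0.14 over 14 genes, inside the random range, with Pfkp at 0.65, Aldoa at −0.53 and Ldha at −0.43. Lipid and cholesterol genes had a median of 0.32 over 14 genes at percentile 95.1, with Lpl, the sterol sensor Insig1 (403 against 112) and the lipoprotein receptor gene Scarb1 (log2 ratio at least 1.13) higher in CCR2+ cells and the fatty acid binding protein gene Fabp5 (836 against 1786) higher in CCR2− cells. With the floor at the 75th percentile this list lay in the highest 2.5% of random lists, at 0.35. Iron and haem genes lay at −0.41 over 14 genes at percentile 3.58, inside the random range, with Slc40a1, Hp and Lcn2 toward CCR2− and the biliverdin reductase genes Blvra (343 against 125) and Blvrb (484 against 223) toward CCR2+. This list lay in the lowest 2.5% under 3 of 10 alternatives, with medians of −0.40 after quantile normalisation, −0.48 with the floor at the 99th percentile and −0.41 against unmatched random lists. Lysosome and cathepsin genes had a median of 0.24 over 18 genes with 0 at least 2-fold apart in either direction, with Ctse at a log2 ratio of at most −0.99, Gusb at 0.95 and Ctsd at −0.89. They lay in the highest 2.5% of random lists here, a placement kept under 4 of 10 alternatives. Cell cycle genes lay at −0.19 over 19 genes, with 11 below 0, 8 above 0 and 0 at least 2-fold apart in either direction. The mitotic genes Ccnb2 and Cdk1 stood at −0.79 and −0.68, and the DNA replication genes Mcm7, Mcm2 and Pcna at 0.34, 0.30 and 0.25. The list kept its place in the lowest 2.5% under 8 of 10 alternatives.

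Ribosomal protein and housekeeping genes served as controls. Ribosomal protein genes had a median of 0.13 over 15 genes, with Rps6 at 0.84 and Rps19 at 0.28. This lay in the highest 2.5% of random lists, since random lists of equally strong signal had a median of −0.33, and the placement held under 7 of 10 alternatives. Housekeeping genes had a median of 0.23 over 12 genes, inside the random range, with Gusb at 0.95 and Tfrc at 0.64. Platelet genes gave −0.10 over 3 genes near the floor, with Gp1bb at 94.5 against 77.4 and Clec1b at 50.5 against 93.7. Their median turned to 0.11 with the floor at the median of all signals or at the 75th percentile. Erythroid, endothelial and stromal, and sex-linked lists had under 3 measured members. Their measured genes were Tfrc (306 in CCR2+, 197 in CCR2−) and Car2 (148 and 214), Igfbp7 (114 and 136) and Xist (2278 and 1874).

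**Figure D2:**
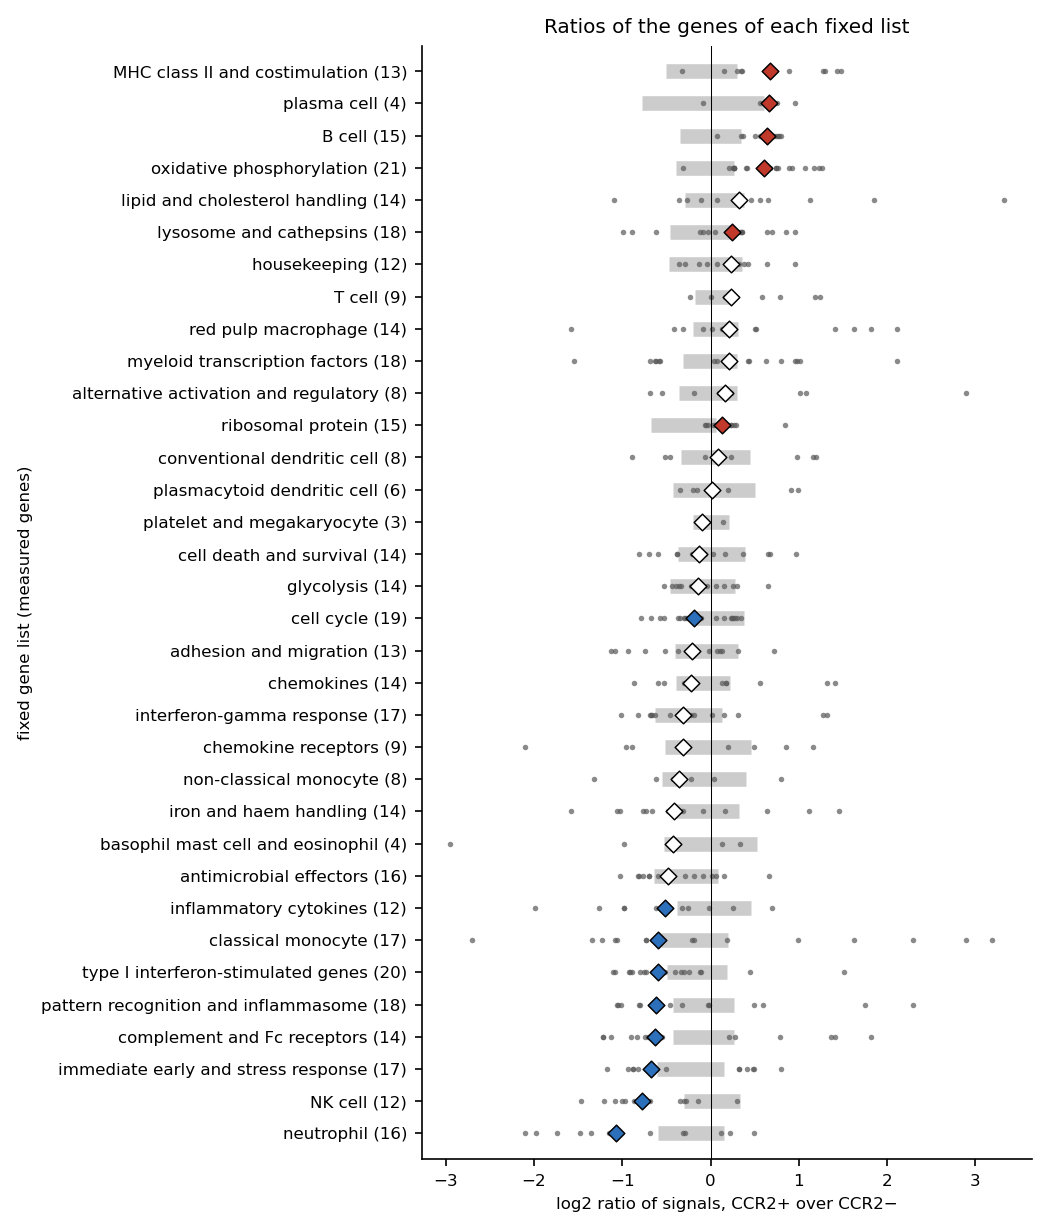
Log2 ratio of signals, CCR2+ over CCR2− (x axis), for the measured genes of each of the 34 ranked gene lists (y axis, number of measured genes in brackets). Grey dots are genes, diamonds are list medians, and grey bars hold the middle 95% of medians of 10000 random lists matched on size and signal. Red diamonds mark the 6 lists in the highest 2.5% and blue diamonds the 9 lists in the lowest 2.5%. Neutrophil markers lie lowest, at −1.07, and MHC class II genes highest, at 0.67.

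As a check within the arrays, 327 of the genes at least 2-fold apart had a second measured probe set. Of these second probe sets, 313 lay on the same side of 0 (95.7%, exact 95% confidence interval 92.9 to 97.6%), and 158 were also at least 2-fold apart (48.3%, 42.8 to 53.9%). Probe sets of 1 gene are not replicates, and the number of arrays limits the precision of every value.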

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

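The spiked controls lie outside the comparison of genes and were looked at because they carried a signal that differed between the arrays. The poly-A spikes Dap, Lys, Phe and Thr, bacterial transcripts added to the RNA before labelling, had a median ratio of 3.35 in favour of the CCR2+ array over 24 probe sets, by the signals as deposited. Of these probe sets, 14 were under the floor of 85.4 on the CCR2− array, 2 of them on both arrays, so this median holds values within background. The 10 at or above the floor on both arrays were a median 3.90-fold higher on the CCR2+ array, from 1.53-fold to 4.17-fold. The hybridisation spikes BioB, BioC and BioD, added after labelling, were a median 1.72-fold higher on the CCR2+ array over 14 probe sets, while the 4 Cre probe sets had a median of 0.98-fold. Since BioB, BioC and BioD were also higher, the poly-A difference need not lie in the labelling alone, though Cre did not share it. Whether less sample RNA or more spike went into the CCR2+ labelling, or a later step differed, was not tested. Each array was scaled as a whole, so the gene ratios are relative to the other transcripts of a sample and do not show a difference in RNA per cell.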

How the results depend on the processing

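All alternatives named here were chosen before the data were examined. No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. With a threshold of 1.5-fold, 1344 genes were higher and 966 lower in CCR2+ cells, and with 3-fold 63 and 86. A looser or stricter limit must change the totals, but the larger side also turned. It was CCR2+ at 1.5-fold and CCR2− at 3-fold, so the near-equal counts at 2-fold (371 and 368) hold for that threshold. With no floor and no filter the counts were 654 and 688 over 18193 genes, since genes near background then count. Of 15 lists placed apart from random lists, 8 stayed so under all 10 alternatives: neutrophil, NK cell, B cell, MHC class II, oxidative phosphorylation, inflammatory cytokines, type I interferon-stimulated genes, and complement and Fc receptors. The other 7 kept their direction, but their medians fell inside the random range under the following settings. Classical monocyte genes did so after quantile normalisation (−0.36), loess (−0.36) and without shared genes (−0.47). Lysosome genes did so after quantile normalisation (0.29), loess (0.26), with a floor at the 99th percentile (0.24), the median of a gene's probe sets (0.24), without probe sets that can take several genes (0.21) and against unmatched lists (0.24). Plasma cell genes did so with a floor at the median of all signals or at the 75th percentile (0.38 in both) and with the median of probe sets (0.58). Ribosomal protein genes did so with these 2 floors and against unmatched lists (0.13 in each). Cell cycle genes did so with the floor at the 99th percentile (−0.11) and against unmatched lists (−0.19), immediate early genes after quantile normalisation (−0.44), and pattern recognition genes with the floor at the median (−0.32). Apart from unmatched lists, which only change the lists compared with, the cause was not tested. Over all list medians, 299 kept their place, 19 left and 16 entered the outer 2.5%, and 5 moved otherwise. Among those that entered were myeloid transcription factor genes (0.29, median of probe sets) and, against unmatched lists alone, non-classical monocyte (−0.36), antimicrobial (−0.48) and interferon-gamma response genes (−0.31). Some medians near 0 turned: chemokine genes to 0.01 (quantile normalisation), alternative activation genes to −0.01 (floor at the 75th percentile), conventional dendritic cell genes to −0.06 (without shared genes), and plasmacytoid dendritic cell genes to as low as −0.15. Of the named genes, Hivep3 (0.16 with the median of probe sets), Arap3 (−0.68) and Suds3 (−0.31), both without probe sets that can take several genes, fell under 2-fold, and 274 other values did not. Htra2, Hdc and Aif1 have only probe sets that can take several genes, so that setting gave no value for them. The share of 2-fold differences in favour of CCR2+ was 50.2% as deposited, 41.9% centred, 47.8% after quantile normalisation and 45.5% after loess. Low signal over background limits every bound, whose size moves with the floor: the log2 ratio of Ccr2 was 2.12 with the floor at the 99th percentile, 2.66 at the 95th and 2.93 at the median of all signals. With the median of its probe sets it was 1.78.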

Other observations

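The tests below use further gene lists that were chosen after the results of the fixed lists had been seen, the span matching of the mitochondrial ribosomal and proteasome lists was added after their medians were known, and the comparison of the NK and B cell lists was chosen only after both were known. Genes of mitochondrial translation were higher in the CCR2+ sample. Of 46 measured mitochondrial ribosomal protein genes, 43 were above 0 and 11 at least 2-fold higher, with a median log2 ratio of 0.80 that no random list reached. Mrpl35 read 377 in CCR2+ and 110.4 in CCR2− cells, and Mrpl28 383 and 123. The 3′ to 5′ signal ratio was also higher in the CCR2+ sample, at 1.26 against 0.99 for Gapdh and 2.14 against 1.32 for Actb. With 1 array per group, a link between it and these genes or those of the proteasome could not be measured. The median log2 ratio of all genes went from 0.10 in the tenth of genes with the shortest genomic span to −0.03 in the longest. Against random lists matched on signal and span, 0 of 10000 were as high as the mitochondrial ribosomal list and 10 as high as the proteasome list. Genes of the proteasome, the complex that degrades tagged proteins, had a median of 0.47 over 31 genes, with 29 above 0, 1 at least 2-fold higher and 13 of 10000 random lists as high. Psmb3 read 879 and 436. The interferon-inducible subunits Psmb8, Psmb9 and Psmb10 stood at −0.36, −0.46 and 0.15.

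In a second list of 22 measured mononuclear phagocyte genes, 5 were at least 2-fold higher in CCR2+ cells and 2 in CCR2− cells. The median of 0.19 lay inside the random range. Ctsc and Ccl9 also stand in fixed lists, and Ccl9, at 1.40, is among the 5. The endolysosomal nuclease gene Pld4 read 1397 in CCR2+ and 405 in CCR2− cells, Ahnak 593 and 177, and the membrane protein genes Ms4a6c and Ms4a6d had log2 ratios of 1.62 each. In the opposite direction the lectin receptor gene Clec4a2 read 237 and 619.5, and Emb 585 and 1191.

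Neutrophil markers were the list furthest toward the CCR2− sample, at a median of −1.07. A trend of the ratio with signal strength does not account for it, since the median was −0.90 after a loess correction and still below all random lists. A larger share of neutrophil RNA in the CCR2− sample is a candidate explanation. A second neutrophil list without a shared gene had a median of −1.07 with all 23 genes below 0. Its 7 genes not also made by monocytes or macrophages (16 are) had a median of −1.31. In the first list, the 10 genes not also made by monocytes or macrophages (6 are) had a median of −1.13. Genes of 1 cell type can vary together, so these lists cannot tell a share from another difference in neutrophil genes. The genes of the first list did not shift alike. It had 13 genes below 0, from Cxcr2 at −2.10 to S100a8 at −0.29, and Mpo, Prtn3 and Elane at 0.11, 0.22 and 0.49. A difference between the macrophages themselves was not tested and stays open, as do the gates, which are not described here.

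MHC class II and costimulation genes were higher in the CCR2+ sample, at a median of 0.67. A lower share of neutrophils alone would raise all other cell types alike. The NK cell median lay below the B cell median by a log2 difference of −1.42, so these lists did not move alike. This comparison was chosen after both medians were known, so it is a description and no independent test. A larger share of B cell RNA is a candidate explanation. A second B cell list had a median of 0.57 with 15 of 19 genes above 0. Its 8 genes not also made by monocytes or macrophages (11 are) had a median of 0.62. Genes of 1 cell type can vary together, so this list cannot tell a share from another difference in B cell genes. Cd40, Cd86, H2-DMa and Ciita, the 4 highest genes of the MHC class II list, stood at 1.47, 1.43, 1.30 and 1.27. The B cell lists reached 0.80 (Blk) and 1.01 (Ly86), so that share alone is not shown to account for these 4 genes. They were picked by size and do not stand for the list. H2-Aa, H2-Eb1, Cd74 and H2-Ab1, at 0.16, 0.30, 0.35 and 0.36, lay below the medians of both B cell lists (0.64 and 0.57). A larger share of mononuclear phagocyte RNA cannot be told apart from no such difference. A second list of their genes had a median of 0.19 at percentile 97.0, with members going both ways. A difference in antigen presentation between the sorted macrophages stays open as untested.

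Oxidative phosphorylation genes were higher in the CCR2+ sample, at a median of 0.60. The tables argue against a trend with the genomic span of genes as the cause, since the list lay 0.56 above the median of random lists matched on signal and span, of which 9 of 10000 were as high. The difference extended to further nuclear-encoded mitochondrial genes, which widens the pattern and does not explain it. A second respiratory chain list had a median of 0.61 with 41 of 43 genes above 0, and the mitochondrial ribosomal genes a median of 0.80. The second list holds further subunits of the same complexes, which can vary together with the first. The proteasome genes were also higher, at a median of 0.47, so the difference was not confined to mitochondrial genes. The length of the transcripts themselves was not analysed here, so the higher 3′ to 5′ ratio of the CCR2+ sample stays open as a source, as do a larger share of another cell type and a difference in metabolism, which were not tested.

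With values under the floor raised to it, 4 probe sets differed by a log2 ratio of at least 6 in size, all higher on the CCR2− array. Besides that of Dnajc28, 3 are unnamed here, with signals of 25995, 17670.4 and 8777 on the CCR2− array and 2.69, 22.5 and 13.95 on the CCR2+ array, so at least 304-fold, 207-fold and 103-fold apart. Whether these are array artefacts was not tested.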
